A study of Mus musculus with 2 samples.

How the data were processed

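Droplet-based 5' single-cell RNA-seq was run on sorted CD4 T cells of photoconverted mesenteric lymph nodes, with 1 D-Red-positive and 1 D-Red-negative library. The deposited matrices hold whole UMI counts per gene and cell barcode, which the authors made with Cell Ranger 7.1.0 on mm10. Each holds 32285 genes, and the annotation used was not stated. No cell type annotation of the authors was used here. The number of mice behind each library was not stated, and nothing in the labels ties a cell to a mouse. Coordinates were taken from the GENCODE annotation of the same build, and the gene identifiers given matched those of the files.

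Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. In D-Red-positive 94 barcodes had too few genes and 18 too many mitochondrial UMIs, and in D-Red-negative 212 and 36. Mitochondrial genes took 2.46% and 2.27% of UMIs of kept cells, and ribosomal protein genes 21.8% and 21.3%. Doublets were scored with Scrublet in scanpy 1.11.5 per library. It marked 2 of 9986 cells, under 0.5%, so the call did not work and doublets remain in the data. As an alternative chosen after this was seen, the 261 and 146 highest-scoring cells, the number expected at 0.8% per 1000 cells, were left out.

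Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were reduced to 30 components, without T cell receptor, immunoglobulin, mitochondrial, ribosomal protein and sex-linked genes. Leiden clustering at resolution 1.0 on 15 neighbours, without integration of the libraries (igraph 0.11.9), gave the clusters. A cluster was named X-like from marker lists fixed before the data were examined, together with the gene lists, the rule for named genes and most of the other settings tried. The naming rule was set after the clusters had been seen. A marker counted when its mean was at least 1.5-fold that of other cells and at least 10% of the cluster's cells had it, and a name needed at least 3 markers, 40% of those measured, and no fewer of its markers among the 10 leading genes than any other class had there. The first version of the rule stopped there and also named clusters 0 (naive), 4 (Tfh), 7 (Th2) and 22 (Th17). The second and final version also asked for a marker of the name among the 10 leading genes, gave no helper T name where at least 50% of cells had a Foxp3 UMI and no T cell name where under 50% had a Cd3e UMI. It left clusters 0, 1, 3, 4, 7, 8, 10, 12, 21 and 22 unnamed. Their shares of D-Red-positive and D-Red-negative cells were 3.59% and 6.42% for cluster 0, 4.17% and 3.89% for cluster 1, 5.41% and 7.33% for cluster 3, 4.78% and 1.43% for cluster 4, 4.03% and 3.72% for cluster 7, 0.280% and 2.22% for cluster 8, and 8.98% and 2.95% for cluster 12. Clusters 10, 21 and 22 are given with the results.

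Shares carry exact Clopper-Pearson 95% intervals. Unless a share is given as unthinned, shares of cells with a UMI were compared between libraries after each cell was thinned to 3000 UMIs, the 10th percentile of the shallower library rounded down, and shallower cells were left out. For summed expression, UMIs were added over the cells of a library and divided by their total (UPM), with exact Poisson intervals for levels and exact conditional intervals for ratios (scipy 1.17.1). These intervals treat UMIs as independent and leave out differences between mice, sorts and libraries, which 1 library per group cannot show. A zero is given as an upper limit from 3 counts. Within Treg-like cells of D-Red-negative 2665580 UMIs were available, and in all kept cells 37886338 (D-Red-positive) and 37380751 (D-Red-negative).

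Named genes were those with at least 20 UPM (all cells) or 50 (within a class) in the higher library, without receptor segments, mitochondrial, ribosomal protein, haemoglobin and unnamed genes. The 12 highest and 12 lowest ratios were taken in all cells and in Treg-like cells, and the 8 highest and 8 lowest in the other sets. Members of the 28 fixed lists serve as examples. Pde1c and Fah across clusters, genes that differed alike in T cells and other cells, Cd74, the other-cell markers by cluster and all values for unnamed clusters were chosen after the data were seen. A list is described by the median log2 ratio of members with at least 5 UPM in the higher library, by the counts at least 1.5-fold apart, and by its place among 10000 random lists of the same size matched on level. The intervals of medians come from 1000 draws of the counts. Which lists lead each comparison was decided after their medians had been seen. T cell receptor use is the summed difference between the libraries' segment shares in the direction of 1 library, with the range that 1000 draws from pooled shares give as counting error. UMIs of 1 segment in 1 cell are not independent, so cells were counted as an alternative.

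The summed comparison was tested on simulated data made from the counts of 10220 genes, 200 of which were doubled or reduced to the same degree. The direction was recovered for 100% of these, 95.2% of intervals held the true ratio, and 6.5% of 200 lists of unchanged genes fell outside the 95% range of random lists. The simulated counts were drawn independently per gene, as the intervals assume, and the unchanged lists were random genes. These figures therefore check the calculation and do not cover lists of co-expressed genes or libraries of different cell mixture. Other settings, chosen before the data were examined, covered resolution, filters, doublets, centring of components per library, receptor segments among the variable genes, thinning, scaling, list minimum and definition of the classes. Alternatives added after the data were seen left out the highest-scoring cells, left the fixed markers out of the variable genes, took Foxp3-rich clusters as Tregs, left these or cluster 21 out of the remaining cells, took Tfh cells by their UMIs for their share, and kept cluster 4 among Tfh-like cells.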

Results

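Single-cell RNA was measured in CD4 T cells of mesenteric lymph nodes. The mice were Vav-H2B-Dendra2 animals, whose blood cells carry a nuclear, histone-fused protein that light converts from green to red. The node was photoconverted, and 7 days later red (D-Red-positive) and non-red (D-Red-negative) cells were sorted from the CD19-negative, CD8-negative, CD4-positive cells with low CD62L. Cells that had been in the node at conversion and had not diluted the red protein by division are D-Red-positive. The D-Red-negative cells had entered later, had not been converted, or had lost the red protein. Each group had 1 library and no replicate, so no test between groups was possible, and every interval below is a 95% interval that covers counting error only. Levels of summed RNA are given as UPM, the UMIs of a gene scaled to a total of 1000000 in the cells compared. The D-Red-positive library held 37990108 UMIs in 5822 barcodes, and the D-Red-negative library held 37547840 UMIs in 4495 barcodes. After filtering, 5713 D-Red-positive cells (median 5824 UMIs) and 4271 D-Red-negative cells (median 7342 UMIs) were kept.

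The first comparison asked which CD4 T cells were over-represented among D-Red-positive cells. Regulatory T cells were the most frequent named class among D-Red-positive cells. Clusters named Treg-like, from the suppressive T cell genes Foxp3, Il2ra and Lrrc32 among others, held 33.5% (32.3 to 34.8) of D-Red-positive cells and 8.41% (7.59 to 9.28) of D-Red-negative cells, a ratio of 3.99. Over the other 10 clusterings the Treg-like share lay between 23.0% and 35.3% of D-Red-positive and between 5.07% and 11.4% of D-Red-negative cells, and over 11 alternatives the ratio between 3.09 and 5.53. Naive or central memory T-like cells went the other way, with 6.60% (5.97 to 7.27) of D-Red-positive and 20.9% (19.7 to 22.2) of D-Red-negative cells. Of these, 358 and 613 were in cluster 6, with 8 markers of the class raised but only Ccr7 among its 10 leading genes. The other 19 and 280 were in cluster 13, which leads with Igfbp4 and Sell. The name rests on RNA only, and the sort had taken cells with low CD62L, the protein of Sell. Th17-like cells, named from genes of the interleukin-17 lineage such as Il23r and Ccr6, were 1.19% of D-Red-positive and 4.68% of D-Red-negative cells. Cycling-like cells, led by Hist1h1b and Mki67, were 0.910% and 4.05% in the same order. An unnamed cluster led by Klf2, Itgb1 and S1pr1 (cluster 10) held 2.78% of D-Red-positive and 16.5% of D-Red-negative cells.

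Tfh-like cells, named from genes of follicular helper T cells such as Cxcr5, Sostdc1 and Il21, were 14.2% (13.3 to 15.2) of D-Red-positive and 9.13% (8.28 to 10.0) of D-Red-negative cells. This order did not hold across settings, since the Tfh-like share was higher in D-Red-positive in 8 of 12 alternatives. Over the other 10 clusterings it lay between 5.15% and 15.2% of D-Red-positive cells and between 4.17% and 13.9% of D-Red-negative cells. Keeping the 2 cells marked as doublets was enough to move the Tfh-like share to 6.09% and 5.03%. The intervals above do not cover this dependence on the clustering. Interferon responding T-like cells were 0.613% (0.427 to 0.851) of D-Red-positive and 1.17% (0.870 to 1.54) of D-Red-negative cells, but higher in D-Red-positive by 2.81 points with the fixed markers left out of the variable genes. Th1-like cells took 0.858% and 0.796%, with overlapping intervals. Cells other than T cells were present in both libraries. Myeloid or dendritic-like cells were 3.68% of D-Red-positive and 3.51% of D-Red-negative cells, and plasmacytoid dendritic-like cells were 0.123% and 1.31%. Shares in these libraries are shares of what the sort let through, and D-Red-positive cells were the shallower ones.

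**Figure D1:**
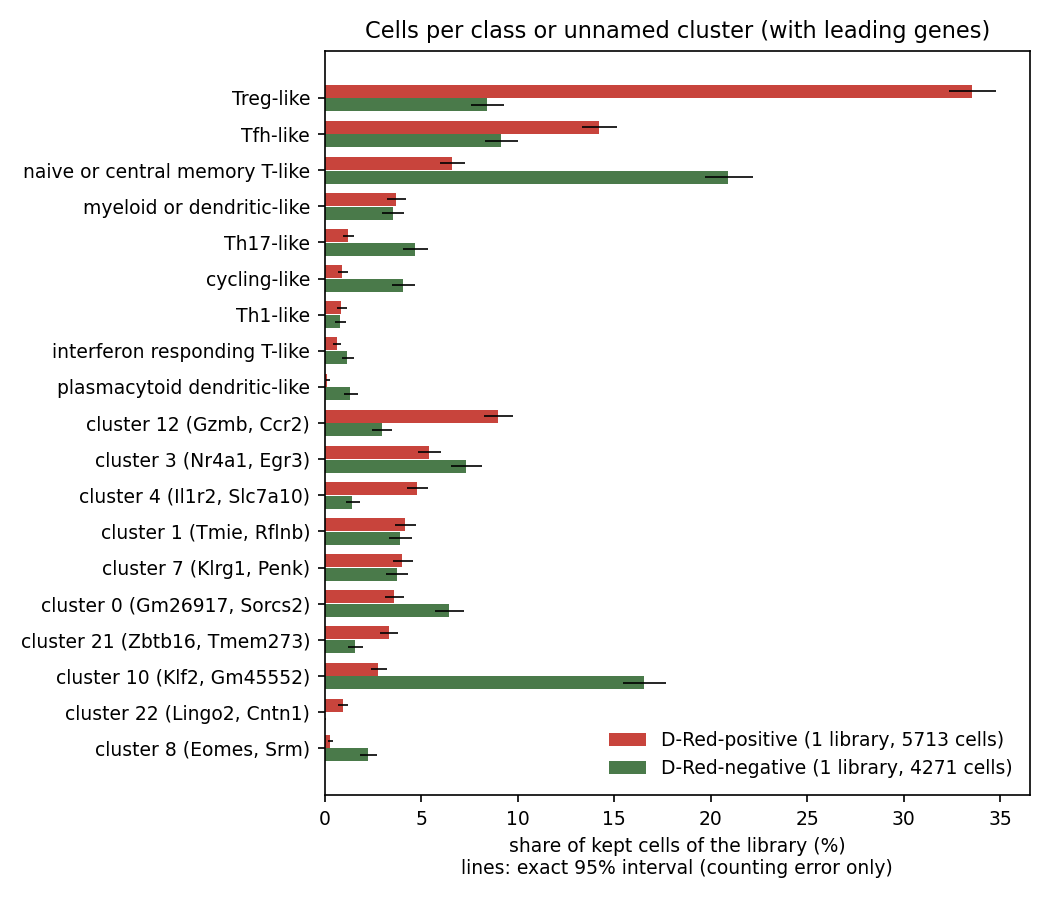
Share of kept cells (%) in each named class and each unnamed cluster, with the leading genes of unnamed clusters in brackets. Bars stand for the D-Red-positive library (5713 cells) and the D-Red-negative library (4271 cells), lines for exact 95% intervals. Treg-like cells reached 33.5% and 8.41%, and cluster 10 reached 2.78% and 16.5%.

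A count that does not rest on clusters gave the same order for Foxp3, the transcription factor that defines regulatory T cells (ENSMUSG00000039521, mm10 chromosome X, 7573644 to 7595245, where the Flicr gene overlaps it on the same strand). With every cell thinned to 3000 UMIs, 39.1% (37.8 to 40.5) of D-Red-positive and 14.8% (13.7 to 15.9) of D-Red-negative cells had a Foxp3 UMI. Thinning left out 523 D-Red-positive and 314 D-Red-negative cells that were shallower. Without thinning the shares were 48.3% and 19.8%. In Tfh-like cells the share with a Foxp3 UMI was 2.18% in D-Red-positive (median 5804 UMIs before thinning) and 0.532% in D-Red-negative (median 7588 UMIs). That share is no measured background, since the naming rule gave no Tfh name to clusters in which most cells had a Foxp3 UMI. Cluster 4, with follicular helper genes and an unthinned Foxp3 share of 68.3%, was left unnamed by it. In cells other than T cells the Foxp3 share was 6.40% (median 8827 UMIs) and 2.44% (median 11211 UMIs). Clusters in which most cells had a Foxp3 UMI (4, 5, 7, 11 and 12), a grouping made after the clusters were seen, together held 51.3% of D-Red-positive and 16.5% of D-Red-negative cells.

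Within Treg-like cells, markers of Treg subsets were compared as shares of thinned cells with a UMI, over 1776 D-Red-positive cells (median 5930 UMIs) and 335 D-Red-negative cells (median 6789 UMIs). Itgae, the integrin CD103 that holds T cells in epithelial tissues, was seen in 51.6% (49.2 to 53.9) of D-Red-positive and 36.4% (31.3 to 41.8) of D-Red-negative Treg-like cells. Ccr7, a chemokine receptor for the T cell zone, was seen in 55.0% (52.7 to 57.3) and 42.1% (36.7 to 47.6). Icos, a costimulatory receptor, was lower in D-Red-positive, at 38.1% (35.9 to 40.4) against 56.4% (50.9 to 61.8), and Ikzf2 was lower at 62.8% (60.5 to 65.1) against 73.7% (68.7 to 78.4). The other 12 markers, among them Rorc, Gata3 and Cxcr5, had overlapping intervals, although without thinning those of Gata3 (30.7% and 38.2%) and Sell (10.3% and 21.4%) did not overlap. In thinned cells with a Foxp3 UMI, Sell (4.44% and 10.0%), Klrg1 (3.40% and 6.75%) and Il1rl1 (0.849% and 2.88%) were lower in D-Red-positive without overlap, and the intervals of Ikzf2 (64.9% and 69.4%) overlapped. Among Treg-like cells Il1rl1, Klrg1 and Il10 each had a UMI in under 2% of thinned cells in both libraries. Foxp3-rich clusters 4, 7 and 12 were left unnamed and lie outside the Treg-like class. Cluster 7 is led by Klrg1 and Il1rl1, and Il10 and Rorc are among the leading genes of cluster 12. The low shares of Il1rl1, Klrg1 and Il10 thus follow in part from the class definition, and the overlaps above hold for clusters 5 and 11 only. Shares in cells other than T cells, among them dendritic-like cells that express Ccr7, were 6.40% and 0.813% for Itgae, 28.5% and 15.4% for Ccr7, 26.2% and 17.1% for Icos, 22.1% and 12.2% for Ikzf2, 4.65% and 35.8% for Sell, 2.33% and 0.813% for Klrg1, and 0.581% and 0 of 123 (up to 2.44%) for Il1rl1, in the order D-Red-positive, D-Red-negative. Itgae, Ccr7 and Sell thus differed in the same direction in cells other than T cells, while Icos and Ikzf2 went the other way. Klrg1 and Il1rl1 were seen in too few of these cells to give a direction. The cells other than T cells were unlike mixtures. Before thinning they included 7 and 56 plasmacytoid dendritic-like cells, and 54 and 0 cells of cluster 22. Unthinned shares were 62.9% and 45.1% for Itgae, 69.6% and 58.8% for Ccr7, 54.4% and 70.8% for Icos, and 77.1% and 82.5% for Ikzf2. Treg-like clusters 5 and 11 mixed alike, with cluster 5 at 61.7% of D-Red-positive and 64.9% of D-Red-negative Treg-like cells. Finer sub-clusters, described further below, were not filled alike. Sub-cluster 0 held 106 of 1916 D-Red-positive and 68 of 359 D-Red-negative Treg-like cells.

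Summed over all cells, D-Red-positive had more RNA of Treg genes and less RNA of recirculation and cell cycle genes. Lrrc32, which displays latent TGF-beta on Tregs, was 6.05-fold higher (5.45 to 6.73), Itgae 3.50-fold (3.34 to 3.66) and Il2ra, the high-affinity interleukin-2 receptor chain, 3.45-fold (3.31 to 3.59). Of the 12 Treg identity genes, 11 were at least 1.5-fold higher and 1 was within 1.5-fold, with a median log2 ratio of 0.97 (0.94 to 1.00). The egress and recirculation list had a median of -0.61 (-0.66 to -0.57) over 10 measured genes, of which 5 were at least 1.5-fold lower and 1, Ccr2, was higher at 1.59-fold. Klf2, a transcription factor that maintains S1pr1 and Sell, had a ratio of 0.229, and S1pr1, the receptor that takes T cells out of lymph nodes, had a ratio of 0.243. Sell encodes CD62L, the protein the sort selected against, and had a ratio of 0.296. All 12 cell cycle genes were at least 1.5-fold lower, with a median of -1.95 (-2.04 to -1.88), and Hist1h1b, Pclaf and Birc5 were 5.98-fold, 5.04-fold and 5.10-fold lower.

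Other named genes of all cells belonged to different groups. Higher in D-Red-positive were Gbp2b (5.12-fold), the mineralocorticoid receptor gene Nr3c2 (4.27-fold), the syndecan gene Sdc4 (4.03-fold), Camk2n1 (3.49-fold), Ddx43 (3.33-fold), the cytokine signalling inhibitor Socs2 (3.28-fold) and Gpr83 (3.26-fold). Lower were Ly6c2 (6.50-fold), Clspn (5.66-fold), Kif11 (5.18-fold), Hist1h1a (4.99-fold), Hist1h2ab (4.87-fold), Cdca3 (4.80-fold) and Ccna2 (4.70-fold), most of them genes of dividing cells. The effector Treg list had a median of 0.53 (8 of 19 genes at least 1.5-fold higher, 1 lower) and the costimulation list 0.59 (6 of 11 higher, none lower). The quiescence and naive state list had a median of -0.40, with 7 of 16 genes at least 1.5-fold lower, among them Igfbp4 and Dapl1. All 14 glycolysis genes were within 1.5-fold, with a median of -0.28.

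Markers of other cell types also differed in these sums. The macrophage genes Apoe and Lyz2 were 7.64-fold (6.86 to 8.52) and 7.49-fold (6.78 to 8.30) higher in D-Red-positive. Cluster 18, which leads with both, held 1.73% of D-Red-positive and 1.55% of D-Red-negative cells and 3086 of the 3312 Lyz2 UMIs of D-Red-positive. Within it Lyz2 was at 9220 UPM in D-Red-positive and 2136 in D-Red-negative. The size of these ratios depended on which barcodes were kept, since all barcodes together had 3518 Lyz2 UMIs in D-Red-positive and 801 in D-Red-negative, and the kept D-Red-negative cells had 436. The plasmacytoid dendritic list had a median of -1.48 (6 of 8 genes at least 1.5-fold lower), with Siglech 5.89-fold lower and Ly6d lower at a log2 ratio of -2.32. The B cell list had a median of 1.14 over 4 measured genes, including Cd79b and Ighm, although the sort excluded CD19-positive cells. The gamma-delta or innate-like T list had a median of 0.79 over 4 genes, and the unnamed cluster 21, led by Zbtb16, held 3.31% of D-Red-positive and 1.55% of D-Red-negative cells. The myeloid or dendritic list had a median of 0.24 over 8 genes, the innate lymphoid list -0.10 over 7 and the CD8 T cell list -0.57 over 3. All 6 sex-linked genes were within 1.5-fold, with a median of 0.01.

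The comparison within Treg-like cells asked how those of D-Red-positive differed from those of D-Red-negative. Treg-like cells were clusters 5 and 11 only, which held 1916 of 2932 D-Red-positive and 359 of 705 D-Red-negative cells of Foxp3-rich clusters. The Foxp3-rich clusters 4, 7 and 12 are counted among the remaining CD4 T cells below, so the values here do not describe all Tregs. D-Red-positive Treg-like cells had less RNA of the genes that let T cells leave the node. S1pr1 was 4.54-fold lower, at 16.4 UPM (14.2 to 18.8) against 74.3 (64.3 to 85.4), and Klf2 was 3.42-fold lower, at 50.9 (47.0 to 55.1) against 174 (159 to 191). S100a6 (4.55-fold), Lgals1 (2.48-fold) and Crip1 (2.18-fold) were lower as well, as was the skin- and tissue-homing receptor Ccr4 (2.39-fold). Rgs1, which dampens chemokine receptor signals, was higher, at 397 UPM (386 to 408) against 203 (186 to 220). Lrrc32 was 2.03-fold (1.75 to 2.36) and Hdac9, a histone deacetylase, 2.92-fold (2.38 to 3.61) higher.

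Grouped by list, Treg-like cells of both libraries had the Treg identity genes at like levels, with a median log2 ratio of 0.02 (-0.04 to 0.08). The class was named from genes of this list, which holds their levels alike in part. Of these 12 genes, 9 were within 1.5-fold, including Foxp3 with a ratio of 1.06, while Il2ra (1.64-fold) and Lrrc32 were higher and Ikzf2 (ratio 0.633) lower. In the egress and recirculation list 6 of 10 measured genes were at least 1.5-fold lower and 1 was higher, with a median of -0.79 (-0.95 to -0.63), below all 10000 random lists matched on level. The higher gene was Ccr7 (1.64-fold). A place at the lower end of random lists was not particular to the egress list. The quiescence and naive state list, which shares Klf2, S1pr1 and Sell with it among others, was also at percentile 0 (median -0.34). The cell cycle list was at percentile 0, effector Treg at 0.11 and glycolysis at 0.15, while Treg identity was at 72.45. Effector Treg genes had a median of -0.22 (-0.30 to -0.11), which was -0.0673 without the cells scored highest as doublets and -0.10 in cells with a Foxp3 UMI, there at percentile 9.65 of random lists. Of its 15 measured genes, Icos (ratio 0.548), Tigit (0.569), Maf (0.588) and Prdm1 (0.634) were at least 1.5-fold lower, Itgae (1.56-fold) was higher and the remaining 10 were within. The cell cycle list had a median of -1.70 (-1.99 to -1.21), with 6 of 7 measured genes lower. Of the lymph node residency and retention genes 3 of 12 were at least 1.5-fold higher (Rgs1, Itgae and Xcl1, the last at 1.59-fold with an interval of 0.843 to 3.31), 1 was lower (Rgs2) and the median was 0.09 (-0.08 to 0.37). Of the 16 measured T cell receptor signalling response genes 15 were within 1.5-fold, with a median of 0.09 (-0.06 to 0.23).

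Further named genes of Treg-like cells, higher in D-Red-positive, were Gpm6b (2.54-fold), Gbp2b (1.93-fold), Pde1c (1.87-fold), the enkephalin gene Penk (1.85-fold), Tnfsf8 (1.81-fold), the interleukin-2 responsive genes Cish (1.80-fold) and Socs2 (1.75-fold), Abi3 (1.73-fold) and Ptger2 (1.70-fold). Penk turned to a log2 ratio of -0.22 when Tregs were taken as cells with a Foxp3 UMI. Lower ones were Sell (2.37-fold), Rora (2.31-fold), Gmfg (2.26-fold), Plcb4 (2.02-fold), Cdk8 (1.95-fold) and Trat1 (1.87-fold). Cdk8 stood at 9388 UPM in D-Red-positive and 18301 in D-Red-negative, and Gm15739 overlaps it on the same strand (mm10 chromosome 5, 146231230 to 146302874). It was lower in 15 of 17 T cell clusters and had ratios of 1.03 and 1.38 in the other clusters with at least 30 cells in each library. Pde1c, a calmodulin-dependent phosphodiesterase, was higher in D-Red-positive by 1.62-fold to 2.02-fold in all 19 clusters that had at least 30 cells in each library, cells other than T cells included. Without receptor, immunoglobulin and unnamed genes, 3209 genes had at least 50 UPM in the higher library, both in T cells and in other cells. Of these, 125 were at least 1.5-fold apart in T cells. In other cells and in the dendritic-like cluster 9, 41 of the 125 were that far apart in the same direction (24 higher, 17 lower in D-Red-positive), and 2 in the opposite direction. Among the 41, with ratios in T cells and cluster 9, were Il2ra (3.39 and 6.21), Serpina3g (2.81 and 1.60), Ctla4 (2.09 and 1.66), Socs1 (1.91 and 4.05) and Gpm6b (1.67 and 1.71). Of markers of other cell types in Treg-like cells, Lyz2 was at 5.59 and 1.13 UPM and H2-Aa at 9.80 and 4.13 UPM in D-Red-positive and D-Red-negative, and the B cell and plasmacytoid dendritic lists had medians of 0.33 and 0.31. In cells with a Foxp3 UMI the median of the myeloid or dendritic list lay between 0.94 and 1.44 (95% interval, 5 of 6 genes higher). H2-Aa, of this list, was 2.67-fold higher there, and H2-Eb1, which is not in the list, 3.53-fold. The median over all genes at the level minimum was -0.03 in this comparison.

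**Figure D2:**
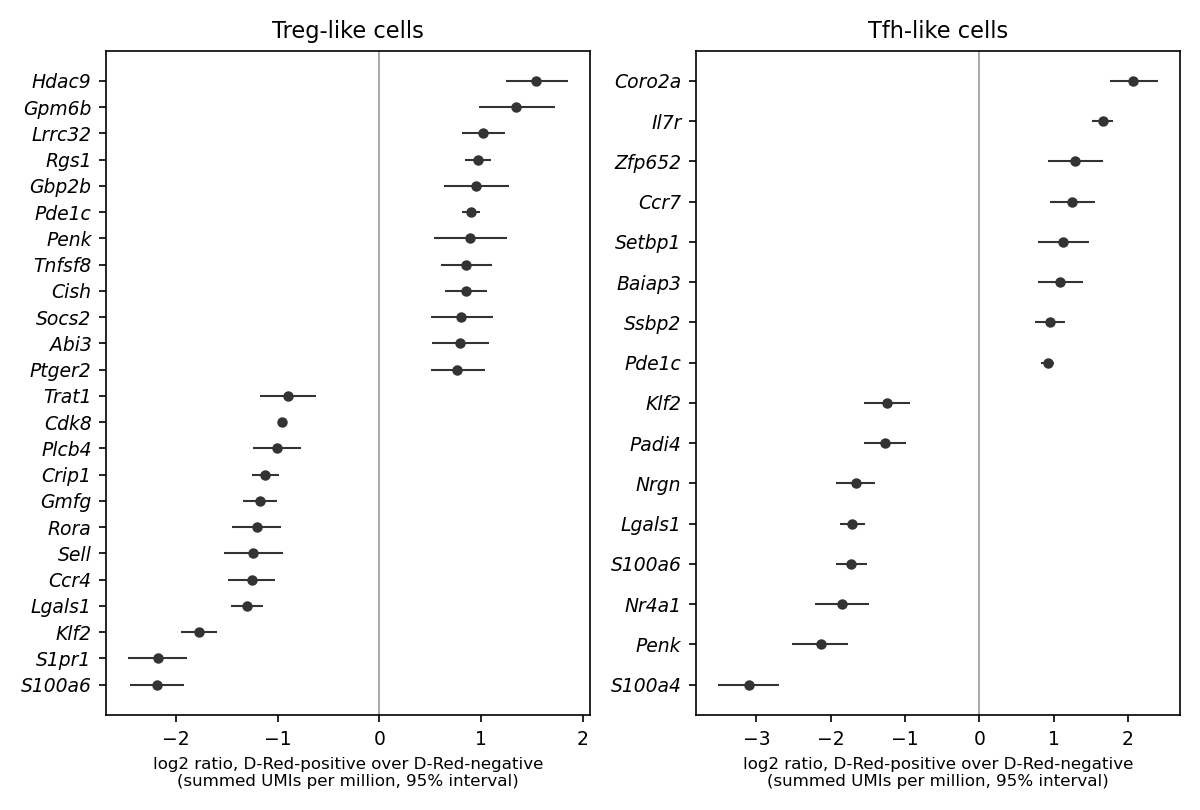
Log2 ratio of summed UPM, D-Red-positive over D-Red-negative, of the genes named by the size rule in Treg-like cells (1916 and 359 cells) and Tfh-like cells (813 and 390 cells), 1 library per group. Points are ratios and lines exact 95% intervals for counting error. Klf2, S100a6 and Lgals1 lie below 0 in both panels, and Pde1c above.

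Tfh-like cells of D-Red-positive had more RNA of the interleukin-7 receptor gene Il7r and less of S100a4 and Nr4a1. Il7r was 3.16-fold higher (2.87 to 3.48), Coro2a 4.20-fold (3.38 to 5.28) and Ccr7 2.38-fold (1.93 to 2.94). S100a4 was 8.54-fold lower, with a ratio of 0.117 (0.0874 to 0.155), and Nr4a1, an early gene of T cell receptor signals, was 3.59-fold lower. Klf2 (2.36-fold), S100a6 (3.30-fold), Lgals1 (3.26-fold), Penk (4.40-fold), Nrgn (3.16-fold) and Padi4 (2.41-fold) were lower too, and Zfp652 (2.44-fold), Setbp1 (2.18-fold), Baiap3 (2.13-fold), Ssbp2 (1.93-fold) and Pde1c (1.89-fold) higher. The T cell receptor signalling response list had a median log2 ratio of -0.29 (-0.46 to -0.17), with 6 of 18 genes at least 1.5-fold lower, such as Cd83 and Nr4a3, and 1, Myc, higher. Egress and recirculation genes went both ways, with a median of 0.02 (-0.14 to 0.16). Follicular helper genes had a median of -0.22, with 11 of 13 within 1.5-fold, and Il21 (ratio 0.609) and Angptl2 (0.638) lower. Th17 genes had a median of -0.86 over 4 measured genes, and Th2 genes -0.64 over 5. Cluster 2 held most Tfh-like cells in both libraries (662 of 813 and 289 of 390). Markers of other cells differed too, with a median of 1.19 over 4 gamma-delta or innate-like T genes (3 higher, 1 lower), which was -1.31 with at least 1000 genes per cell, and of 0.37 over 11 Treg identity genes (5 higher, none lower). Taken as cells without a Foxp3 UMI and with a Cxcr5 or Bcl6 UMI, Ccr7 had a log2 ratio of -0.07, Nrgn 0.03 and the follicular helper list 0.24. The same cells gave the Th17 list 0.13, egress and recirculation -0.34 and receptor signalling response -0.15. With at least 1000 genes per cell Coro2a had -0.08, the follicular helper list 0.43 and egress and recirculation -0.35. The follicular helper list was at 0.12 when only the 2 cells marked as doublets were kept in addition.

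The remaining CD4 T cells, those in T cell clusters that were neither Treg-like nor Tfh-like, had higher Treg genes and lower recirculation and cell cycle genes in D-Red-positive. The libraries filled this set with different clusters. Of 2713 D-Red-positive and 3316 D-Red-negative cells, 159 and 706 were in cluster 10 (led by Klf2), 19 and 280 in cluster 13 (led by Igfbp4 and Sell), 52 and 173 in the cycling-like cluster, 513 and 126 in the Foxp3-rich cluster 12, and 189 and 66 in cluster 21, which is led by Zbtb16, Xcl1, Cxcr6 and gamma-delta receptor genes among others. All 12 Treg identity genes were at least 1.5-fold higher, with a median of 1.34 (1.27 to 1.39), among them Foxp3 (3.36-fold) and Ctla4 (2.48-fold). Unnamed Foxp3-rich clusters (4, 7 and 12) belong to this set, and without them the median was 1.04 (0.95 to 1.11). Of the effector Treg genes 14 of 19 were at least 1.5-fold higher, led by Il10 (6.15-fold), with a median of 0.84 that was 0.20 without those clusters. Lymph node residency and retention genes had a median of 0.80, with 8 of 14 higher, including Cxcr6 (1.85-fold), Rgs1 (2.30-fold) and Itgae (3.45-fold), and 0.71 without those clusters. Without cluster 21 the median was 0.62 (0.39 to 0.79), with 7 of 13 higher and Cxcr6 within 1.5-fold (ratio 1.18), and the gamma-delta or innate-like T list was at 0.33 over 3 genes. Klf2 was 4.04-fold (ratio 0.234 to 0.261) and S1pr1 3.54-fold lower, and the egress and recirculation list had a median of -0.55 (5 of 10 lower, 1 higher) and of -0.75 without the Foxp3-rich clusters. All 12 cell cycle genes were at least 1.5-fold lower, with a median of -1.47.

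By size the genes with the highest ratios in the remaining CD4 T cells were Gbp2b (8.62-fold), Sdc4 (7.74-fold), Frmd5 (4.88-fold), Socs2 (4.07-fold), Setbp1 (3.92-fold), Prg4 (3.71-fold), Serpina3g (3.60-fold) and the chemokine receptor Ccr5 (3.56-fold). Besides Klf2 and S1pr1 the lowest were Hist1h1b (4.26-fold lower), Birc5 (3.56-fold), Hist1h2ab (3.53-fold), Nebl (3.49-fold), Pclaf (3.43-fold) and Anxa2 (3.36-fold). Markers of some other cell types were higher here in D-Red-positive. Medians were 1.65 over 4 measured myeloid or dendritic genes, 1.47 over 5 B cell genes and 1.40 over 5 gamma-delta or innate-like T genes. Other such lists differed less. The CD8 T cell list had a median of 0.42 over 4 genes, 1 of them at least 1.5-fold higher. The innate lymphoid list had 0.21 over 6 genes (3 higher, 1 lower). The plasmacytoid dendritic list had 0.08 (-0.03 to 0.20) over 4 genes (1 higher, none lower). Cd74, of antigen presentation, was 2.88-fold higher, and 19.8% (18.7 to 20.9) of D-Red-positive and 12.2% (11.2 to 13.3) of D-Red-negative thinned cells in T cell clusters had a Cd74 UMI. The corresponding shares for Lyz2 were 1.39% and 0.469%.

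**Figure D3:**
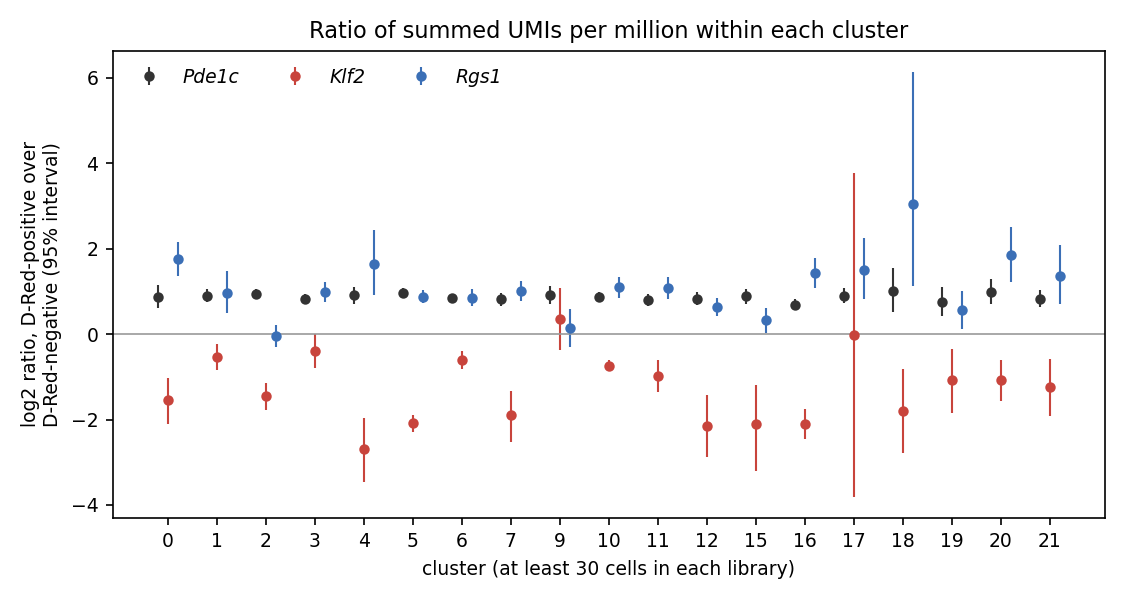
Log2 ratio of summed UPM, D-Red-positive over D-Red-negative, for Pde1c, Klf2 and Rgs1 within each cluster that had at least 30 cells in each library (19 clusters, 1 library per group). Points are ratios and lines exact 95% intervals for counting error. Pde1c lies above 0 in all 19 clusters, Klf2 below 0 in 18 and Rgs1 above 0 in 18.

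T cell receptor segments were compared to see whether the libraries drew on like repertoires. Trbv3 took 16.2% (16.0 to 16.5) of Trbv UMIs in D-Red-positive and 11.2% (11.0 to 11.4) in D-Red-negative (ENSMUSG00000076463, mm10 chromosome 6, 41048290 to 41048828). Within Treg-like cells it took 18.8% (18.3 to 19.3) and 11.7% (10.9 to 12.6). Trbv13-2 was lower in D-Red-positive, at 11.8% against 13.5%, as was Trbv12-2, at 2.82% against 4.45%. Summed over 35 segments, 8.91% (8.47 to 9.47) of Trbv use differed between the libraries, and counting error alone gives up to 1.22%. In Treg-like cells 16.4% (15.1 to 17.9) differed, where counting error alone gives up to 3.36%. Counted as cells with a UMI of the segment, which removes the weight of cells with many UMIs, 6.20% differed in all cells, against up to 3.67% from counting error. In Treg-like cells that count gave 10.8% against up to 10.4%. Over 128 Trav segments 11.8% of UMIs differed, where counting error alone gives up to 3.13%, and by cells 8.47% against up to 6.80%. In Treg-like cells the Trav count by cells, 18.5%, lay within the 19.7% that counting error gives.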

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

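This result and the genes that describe it were chosen after the data were seen, apart from the innate lymphoid list, and no technical or biological explanation was tested. Cluster 22 held 54 cells, all in the D-Red-positive library, and drew attention as a signal in cells that the T cell comparisons do not use. D-Red-negative had 0 of 4271, which allows a share of up to 0.0702%, against 0.945% of D-Red-positive cells. With 1 library per group, a cluster of 1 library is not shown to be a cell type of its own. Without thinning, its cells (median 7936 UMIs) had a UMI of Il7r in 100%, Cd4 in 92.6%, Fcer1g in 87.0%, Il23r in 83.3%, Kit in 77.8%, Rorc in 77.8%, Kcnk1 in 74.1%, Il1r1 in 72.2% and Cd7 in 72.2%, while 20.4% had Cd3e. Other members of the innate lymphoid list were seen in fewer of them, Tyrobp in 35.2%, Arg1 in 14.8%, Ncr1 in 5.56% and Gzma in 0%. Other kept cells, of both libraries and also unthinned, had Il7r to Cd7, in the order given, at 43.0%, 78.0%, 4.01%, 2.43%, 1.72%, 6.41%, 0.0201%, 2.97% and 6.32%, and Cd3e at 93.6%.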

How the results depend on the processing

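Settings were chosen before the data were examined unless a sentence says "added". Shares of cells are given as D-Red-positive, then D-Red-negative, and lists as median log2 ratios. The cause was not tested for any value below that moved or reversed.

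The Treg-like share stayed higher in D-Red-positive in 11 of 11 alternatives. It moved to 28.1% and 5.08% at resolution 1.5, 27.4% and 5.07% with at least 200 genes, 30.1% and 6.72% with at least 1000 genes, 27.7% and 5.17% with at most 5% mitochondrial UMIs, 30.3% and 7.05% with marked doublets kept, 23.0% and 6.09% with components centred per library, and 31.3% and 7.26% with receptor segments among the variable genes. Added settings gave 27.9% and 5.53% without the highest-scoring cells, 35.3% and 11.4% without the fixed markers among the variable genes, and 51.3% and 16.5% for Foxp3-rich clusters.

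The Tfh-like share reversed to 6.91% and 8.61% with at least 200 genes, 9.13% and 11.2% with at least 1000 genes, 7.86% and 11.3% with centred components, and, added, 23.2% and 30.7% for cells without a Foxp3 UMI and with a Cxcr5 or Bcl6 UMI. It kept its direction but moved to 15.2% and 13.9% at resolution 0.5, 5.85% and 4.75% at resolution 1.5, 6.93% and 5.68% with at most 5% mitochondrial UMIs, 6.09% and 5.03% with marked doublets kept, and 7.25% and 5.64% with receptor segments. Keeping marked doublets added only 2 cells to the 9984 kept, so the Tfh-like share was not stable to a change this small. Added settings gave 6.01% and 4.68% without the highest-scoring cells, 5.15% and 4.17% without the fixed markers, and 19.0% and 10.6% with cluster 4. The number of other named classes higher in D-Red-positive moved to 1 at resolution 1.5, 0 with at least 200 genes, 1 with at least 1000 genes, 1 with at most 5% mitochondrial UMIs, 1 with centred components and, added, 1 without the highest-scoring cells. The interferon responding T-like share reversed to a difference of 2.81 points without the fixed markers (added).

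The share of cells with a Foxp3 UMI was 48.3% and 19.8% without thinning, 27.5% and 10.5% with thinning to 1500 UMIs, and 22.4% and 8.11% with at least 2 Foxp3 UMIs. Trbv use differed by 16.4% in Treg-like cells and 6.20% counted by cells.

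In all cells the egress and recirculation list moved to -0.38 with a total without mitochondrial, ribosomal protein and receptor genes and to -0.41 with cells weighted equally, where Treg identity moved to 0.94. In Treg-like cells, taken as cells with a Foxp3 UMI, effector Treg moved to -0.10 and egress to -0.62, and Penk (-0.22) and the plasmacytoid dendritic list (-2.72) reversed. For Foxp3-rich clusters (added) these lists were -0.30, -0.60 and, reversed, -0.17. The plasmacytoid list also reversed without a level minimum (-0.46). Without the highest-scoring cells (added) effector Treg moved to -0.0673, and with marked doublets kept the follicular helper list reversed to 0.0172.

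In Tfh-like cells with at least 1000 genes egress moved to -0.35, and follicular helper (0.43), inhibitory receptors (0.15), interferon (-0.0156), gamma-delta (-1.31) and Coro2a (-0.0847) reversed. By Cxcr5 or Bcl6 UMI, egress moved to -0.34 and receptor signalling to -0.15, and effector Treg (0.22), follicular helper (0.24), Th17 (0.13), inhibitory receptors (0.36), survival (0.0485), Ccr7 (-0.0689) and Nrgn (0.0288) reversed. Follicular helper reversed to 0.12 with marked doublets kept and to 0.10 without the highest-scoring cells (added).

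In the remaining CD4 T cells Treg identity moved to 1.18 and egress to -0.37 with at least 1000 genes, where Th17 reversed to 0.20. Treg identity was 1.20 with marked doublets kept, 1.18 without the highest-scoring cells (added), 1.04 without Foxp3-rich clusters (added) and 1.43 without cluster 21 (added), where cytotoxicity reversed to -0.000157, and egress was -0.75 without Foxp3-rich clusters and -0.65 without a level minimum. Of 656 values of named genes 4 turned direction and 473 stayed within the counting interval, and 17 of 480 values of lists outside the middle of random lists turned.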

Other observations

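The unnamed clusters were compared and the genes named in this paragraph chosen only after the data were seen. In cluster 7, a Foxp3-rich cluster led by Klrg1 and Il1rl1 (230 D-Red-positive and 159 D-Red-negative cells), Penk was 5.47-fold higher in D-Red-positive (4.63 to 6.49). The granule protease gene Gzma was 42.8-fold lower there, at 5.44 UPM (UMIs scaled to a total of 1000000) against 233, Gzmb 7.85-fold and Ccr2 5.86-fold lower. Cluster 7 was 7.84% of Foxp3-rich cells in D-Red-positive and 22.6% in D-Red-negative, although of all cells it was 4.03% (3.53 to 4.57) and 3.72% (3.18 to 4.33), with overlapping intervals. In cluster 12, a Foxp3-rich cluster led by Gzmb, Ccr2 and Il10 (513 and 126 cells), 11 of 17 T cell receptor signalling response genes were at least 1.5-fold higher in D-Red-positive and none lower, with a median log2 ratio of 0.63 (0.52 to 0.89). Cd83 was 2.70-fold, Nfkbid 2.10-fold and the survival gene Bcl2 4.09-fold higher. The dissociation stress list went the same way there, with a median of 0.15 (0.08 to 0.42), 3 of 13 genes higher and Dusp1 2.31-fold higher. In cluster 4, a Foxp3-rich cluster with follicular helper genes (273 and 61 cells), Klf2 was 6.51-fold lower. The follicular helper list had a median of -0.24 there, although of 13 measured genes 3 were at least 1.5-fold higher, 1 lower and 9 within. In cluster 10, S100a4 was 8.18-fold lower and Itgb1 had a ratio of 0.245, while Rgs1 was 2.14-fold higher.

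Of the tests in the next 3 paragraphs, those of sub-clusters of Treg-like cells and of Pde1c against depth were set before their results were seen, and the others were chosen after, those on division and on free RNA for Klf2 in a form revised again and that on recirculating cells with a stricter rule once earlier values were known. The first pattern is the larger share of cells with a Foxp3 UMI in D-Red-positive, whose cells were the shallower ones. Recirculating cells that fill the D-Red-negative library cannot be told apart: without the clusters led by Klf2 or S1pr1 the ratio of Foxp3-rich shares among T cells went from 3.11 to 2.43, but in the 16 T cell clusters left with at least 30 cells in each library Klf2 was still lower in D-Red-positive, in 14 with its interval below 1. Loss of the red protein by division cannot be told apart either. In thinned cells a Foxp3 UMI was seen in 14.6% (5.57 to 29.2) of cycling-like against 40.4% (39.1 to 41.8) of other T cells in D-Red-positive, and in 8.92% (4.96 to 14.5) against 15.4% (14.3 to 16.6) in D-Red-negative, a ratio of 0.578 with intervals that overlap, and past division leaves no mark in the counts. Longer residence of Tregs, the difference the sort was designed for, stays open and was not tested on its own.

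The second pattern is the lower level of Klf2, S1pr1, S100a6, Lgals1 and Crip1 within classes in D-Red-positive. For Klf2, S1pr1 and Lgals1 free RNA from other cells is excluded as the whole cause, since the upper bound of their lowest level in D-Red-negative clusters of other cells at least as deep as Treg-like cells (median 6552 UMIs) was at most 0.527 times the gap between the libraries in Treg-like cells, while for S100a6 and Crip1 the values free RNA needs are present, with that bound at 7.26 and 2.24 times the gap, so it stays open, although dendritic-like cells may express these genes themselves. A mixture of cells finer than the clusters is not bounded, since cells within a sub-cluster can still be mixed. Treg-like cells were split into 17 sub-clusters without these genes, and the 11 with at least 10 cells in each library were compared. The median of the set over them was -1.12, against -1.78 over all Treg-like cells. It was below 0 in all 11 and ranged from -2.12 to -0.22, the last with an interval of -0.82 to 0.32. The difference thus remained at this resolution but was smaller. The libraries filled the sub-clusters unlike. Sub-cluster 0 (median -2.12) held 106 D-Red-positive and 68 D-Red-negative cells, and sub-cluster 8 (median -0.22) held 187 and 28. The sub-clusters left out, mostly of D-Red-positive cells, were not compared. A difference that all cell types of the libraries share cannot be told apart. In the dendritic-like cluster 9 the set had a median of -0.61 (-0.74 to -0.02), between 0 and the -1.55 of T cells. Ratios there were 0.655 for Crip1, 0.270 for S1pr1, 0.549 for Lgals1, 1.27 for Klf2 and 1.24 for S100a6. In cluster 18, shallower at medians of 1538 and 1083.5 UMIs, Crip1 was at 0.656, S1pr1 at 0.529, Lgals1 at 0.279 and Klf2 at 0.288, with no ratio for S100a6. A lower level of this set in Tregs that stayed in the node is a hypothesis, found and tested on the same 2 libraries, and differences of sort or library preparation stay open.

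The third pattern is the higher level of Pde1c and Fah in D-Red-positive, in all 19 clusters with at least 30 cells in each library, as 2 of the 41 genes at least 1.5-fold apart in the same direction in T cells and other cells, of which Rabac1 and Igf1r (higher) and Lgals1, Adk and Aff3 (lower) also went 1 way in all 19 clusters, and the tests below cover Pde1c and Fah only. A different mixture of these clusters is excluded as the whole cause for Pde1c, since its lowest ratio over them was 1.62. For Fah the ratio was above 1 in 19 clusters with its interval above 1 in 18. A different mixture of cells within the clusters was not tested. Free RNA cannot be told apart by depth, although the rule set beforehand was met. That rule counted against free RNA if the deepest cells of both libraries had at least 2 times the Pde1c UMIs of the shallowest. It cannot decide, for the reason given after the values. Pde1c UMIs per T cell were 3.51 times as many in the deepest as in the shallowest of 4 equal groups of D-Red-positive cells. In D-Red-negative they were 5.36 times as many. All UMIs per cell were 3.47 and 4.31 times as many in the same groups. Pde1c made by the cells themselves would grow with depth whether or not free RNA added to the difference between the libraries. A difference that all cell types of the libraries share is consistent with a Pde1c ratio in other cells that was 1.01 times (0.919 to 1.12) that in T cells, and 1.05 times (0.822 to 1.35) for Fah, although the Fah ratios spread more, from 1.33 to 3.77 over T cell clusters and at 1.62 and 3.99 in the others. Whether it lies in the mice, the sort or the library preparation was not tested.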
